A study of Mus musculus with 12 samples.

How the data were processed

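RNA of mouse colon and skin was hybridised to 1-colour Affymetrix Mouse Gene arrays, per the labels' protocols. There were 12 arrays: 3 wild-type and 3 Adam17 knockout samples of each of 2 tissues. The deposited values are log2 expression values per transcript cluster, and the submitters' processing notes name RMA, which corrects the background, applies quantile normalization and summarises the probes of a cluster. Its version and the probe annotation used for it are not given in the sources used here. RMA values carry no detection call, so genes near the floor cannot be told from absent ones. Samples were grouped by the tissue and genotype in the titles, and the numbers in the titles name the samples.

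The table held 35557 clusters. The platform annotation of the year 2016 gave 1 gene symbol for 21789 of them, several for 1621 and none for 12147. Clusters with several symbols or none are not named. Of the clusters with 1 symbol, 21698 matched the gene table of the GRCm38.p6 assembly by gene number, and 0 symbols changed. That table served only for names and for which genes neighbour each other. Genes were tested where a cluster had 1 symbol and lay above the 20th percentile of its own array in at least 3 of 12 arrays. The cluster with the highest mean stood for a gene with several clusters, which left 18037 genes.

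Comparisons were fitted with limma 3.58.1 in R 4.3.3, as 4 group means over all 12 arrays with 8 residual degrees of freedom and a shared spread, by lmFit and eBayes with default settings. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p of 0.05. The same models were fitted on the 6 arrays of each tissue alone, with 4 residual degrees of freedom. The difference between tissues was the skin change minus the colon change. Single values were compared by an exact permutation test, which for 3 against 3 samples cannot go below 0.1.

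Before the data were examined, 38 gene lists of pathways and cell types were written down, with 859 named members, of which 773 were measured. The sex-linked list served as a check of the samples and the other 37 were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Tests were repeated with the correlation estimated from the data and with fry, which asks whether a list moves on balance in 1 direction and does not compare it with other genes. Counts adjusted over the list alone use the p-values of that list's members. Some lists share members, such as Slpi, Reg3g, S100a8, Retnlb and Ang4, so their calls are not independent of each other. The median log2 fold change, the mean and the test differed in sign only for lists that did not shift. Genes were named by a rule written before the data were examined: Adam17, then up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold whose arrays did not overlap between genotypes, filled to 6 by p where fewer passed, 6 per direction for the difference between tissues, up to 4 members per list by p, genes called in both tissues and called neighbours of Adam17. Unnamed gene models, olfactory receptors and segments of immunoglobulin and T cell receptor genes were counted and not named. Values per array of the neighbouring Skint genes were chosen after their values were seen. Neighbours of Adam17 were counted within 20 Mb, with 10 and 40 Mb as alternatives, by Fisher's exact test.

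The procedure was tested on simulated data with 200 of 18037 genes changed, in 10 simulations. With the spread of the colon arrays, 59.9% of log2 changes of 1 and 91.6% of changes of 2 were recovered, and 5.0% and 3.8% of the calls were false. With the spread of the skin arrays, 67.6% and 92.2% were recovered, and 45.0% and 42.0% of the calls were false, because the shared estimate is too small for skin. In every simulation a shifted list was recovered. Its genes were simulated independently of each other, so lists of co-expressed genes were not tested.

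The alternatives were no filter, a filter at the 50th percentile, every cluster on its own, eBayes with a trend and robust settings, array weights, arrays centred on the median of the genes tested, quantile normalization within each tissue, an added 2-fold limit, sex-linked genes left out, each array left out in turn, the number in the titles as a block and the 6 arrays of a tissue alone. A sign change of a value that passed the threshold in neither setting was not counted as a reversal. Added after seeing the data were fits without the arrays numbered 5, a fit of skin with each array's mean of the hair list as a covariate, and a fit of the colon arrays without the array numbered 6. For the gene lists, centring on the median and the number as a fixed block were also added then. Genes with close paralogs, such as the Ces2, Cyp2c, Oas, Klk1b, Skint, Krtap and Sprr genes, may share probes, so their values are uncertain one by one.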

Results

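Gene expression was measured in whole pieces of mouse colon and skin from wild-type animals and from animals labelled as knockouts of Adam17, the membrane metalloprotease that sheds tumour necrosis factor and several ligands of the epidermal growth factor receptor. There were 12 arrays in 4 groups of 3, with colon and skin of each genotype. The wild-type samples carry the numbers 1, 3 and 5 and the knockout samples the numbers 2, 4 and 6 in both tissues. The values are log2 expression values, and the array medians lay between 4.15 and 4.38. In colon the knockout medians, from 4.25 to 4.28, all lay above the wild-type ones, from 4.15 to 4.19. The number of arrays limits the precision of each comparison. The labels do not say that the samples of a group came from separate mice, so the p-values measure the spread between these samples. Within colon, arrays of the same group correlated at a mean r of 0.986 across clusters and arrays of different genotype at 0.981. Within skin the corresponding values were 0.960 and 0.962, so skin arrays of the same genotype were no more alike than skin arrays of different genotype. Xist was low and the Y-linked genes were high in the arrays numbered 5 of both tissues, which are wild type. In colon, Xist was 2.35 in that array and 7.15 or more in the other colon arrays, and the Y-linked gene Eif2s3y was 6.28 there and 1.42 or less in the others.

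Adam17 was lower in the knockout arrays of both tissues. In colon its log2 level was 6.74 ± 0.15 (SD, n = 3) in wild type and 4.54 ± 0.30 (SD, n = 3) in knockout, a log2 fold change of -2.20 with a standard error of 0.27 (limma adjusted p = 0.011). In skin the levels were 7.32 ± 0.34 (SD, n = 3) and 5.30 ± 0.56 (SD, n = 3), a log2 fold change of -2.01 with a standard error of 0.27 (limma adjusted p = 0.036). The knockout level corresponded to 21.8% of the wild-type level in colon and 24.8% in skin. Every knockout array lay below every wild-type array of its tissue, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples can give. The highest knockout value was that of the sample numbered 6 in both tissues, at 4.82 in colon and 5.94 in skin. The change did not differ detectably between the tissues (skin minus colon 0.18, standard error 0.39, limma adjusted p = 0.96). The colon call was lost without wild-type colon 1, 3 or 5 or knockout colon 4 (highest limma adjusted p = 0.084, range over the alternatives from 2.0e-05). The skin call was lost when the 6 skin arrays were fitted alone (limma adjusted p = 1.00, range over the alternatives from 1.8e-04) and in 10 of the 12 fits that left out 1 array, all but those without wild-type skin 5 or knockout skin 6. The part of the gene that was altered is not given in the labels used here.

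**Figure D1:**
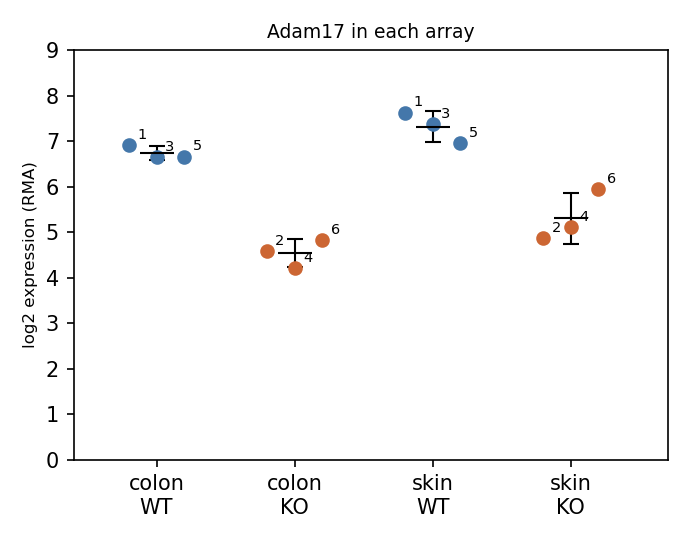
Log2 expression of Adam17 in each of the 12 arrays (points, with the number in the sample title), by tissue and genotype; the horizontal bar is the group mean and the whiskers are 1 SD. The colon knockout arrays lie between 4.22 and 4.82 and the colon wild-type arrays between 6.64 and 6.91, and the skin knockout arrays lie between 4.87 and 5.94 and the skin wild-type arrays between 6.95 and 7.63.

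The first comparison asked which genes differ between knockout and wild-type colon. In knockout colon, Gdpd3, the B cell gene Cd79a, the interferon-inducible gene Ido1 and the cytokine gene Il17b rose, and the cytochrome genes Cyp2c65 and Cyp2c68, the channel gene Kcnf1 and Dzip1 fell, and these 8 calls held with any 1 array left out. Among 18037 genes, 32 passed the threshold, of which 10 were higher and 22 lower in knockout, and in all 32 the knockout arrays lay on 1 side of the wild-type arrays. The strongest rise was that of Gdpd3, a lysophospholipase D, from 3.40 ± 0.51 to 7.10 ± 0.59 (SD, n = 3), a 13.0-fold change (limma adjusted p = 0.0019). The kallikrein gene Klk1b22 rose by 2.53 on the log2 scale (standard error 0.34). Cd79a, which encodes a signalling chain of the B cell receptor, rose by 2.16 (standard error 0.24), and Fcrla, another B cell gene, by 1.01 (standard error 0.14). Ido1, the interferon-inducible enzyme that degrades tryptophan, rose by 2.16 (standard error 0.20, limma adjusted p = 0.0019), and Oas3, an interferon-inducible sensor of double-stranded RNA, by 2.12 (standard error 0.34, limma adjusted p = 0.040). The remaining named rises were Ly6d at 1.48, Myl7 at 1.41, the cytokine gene Il17b at 1.28 and Gimap3, a GTPase gene of lymphocytes, at 0.99.

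The falls in knockout colon were led by Ces2a, a carboxylesterase gene, at a log2 fold change of -2.51 (standard error 0.41), with Ces2b at -1.63. Of the cytochrome P450 genes, Cyp2c55 fell by 2.32, Cyp2c68 by 2.05 and Cyp2c65 by 1.78 on the log2 scale. These genes have close paralogs, and probes may be shared between them. Kcnf1, a potassium channel subunit gene, fell from 6.10 ± 0.28 to 3.85 ± 0.11 (SD, n = 3), with the smallest adjusted p of the comparison (limma adjusted p = 0.0014). Mep1a, which encodes the brush border protease meprin alpha, fell by 1.86, and Ceacam20, another brush border gene, had a log2 fold change of -1.35. These were the 2 of 32 measured markers of absorptive colonocytes that fell, and the list as a whole had a mean log2 fold change of -0.21 that missed the threshold (camera adjusted p = 0.14). Other falls were the hormone gene Ppy at -1.73, Itih2 at -1.67, Nlrp9b at -1.59 and Dzip1 at -1.57. Apart from the 8 stable calls, the named colon calls were lost in 4 to 10 of the 12 fits that left out 1 array, with Ces2a lost in 10, Oas3 in 9 and Ces2b and Mep1a in 7 each. Each of them was lost without wild-type colon 3 and held without knockout colon 6.

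Of 37 gene lists fixed before the data were examined, 12 shifted in colon by camera with its preset correlation, 10 of them upwards. The 27 measured interferon response genes were all higher in knockout colon, with a mean log2 fold change of 1.32 (camera adjusted p = 1.8e-20). This call was lost with an estimated correlation (adjusted p = 0.25). Of these genes, 1 rose over all genes tested, 15 rose adjusted over the list alone, and 17 rose over all genes when the 6 colon arrays were fitted alone. Oasl2 was at 2.26, Psmb8 at 1.31 and Psmb9 at 1.04, and each passed on the colon arrays alone but not over all 12 arrays. The list mean was 5.10 ± 0.03 in wild type and 6.42 ± 0.47 in knockout (SD, n = 3), and the lowest knockout array was number 6 at 5.90. The list of B and plasma cells shifted upwards by a mean of 0.81, with 18 of 19 members higher, 2 that rose over all genes and 14 that rose adjusted over the list alone. Its call held with an estimated correlation (adjusted p = 0.021). Cd79b had a log2 fold change of 1.36 and Ms4a1 of 1.78, both short of the threshold over all genes.

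The enteroendocrine list, the hormone-secreting cells of the gut epithelium, shifted downwards by a mean of -0.45, with 2 of 18 members that fell over all genes, 8 that fell adjusted over the list alone and 2 with higher values. Chga had a log2 fold change of -1.01 (limma adjusted p = 0.044) and Insl5 went from a mean of 9.68 to 8.68 (limma adjusted p = 0.048), calls lost in 7 and 9 of the 12 fits that left out 1 array, while Pyy was at -0.79 and missed the threshold (limma adjusted p = 0.081). This call also held with an estimated correlation (adjusted p = 0.021). It and the B and plasma cell list were the 2 of the 12 colon calls that did.

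Each of the other colon calls was lost with an estimated correlation. Those of cytokines and chemokines and of wound and stress genes were also lost with quantile normalization within each tissue. Antimicrobial and host defence genes were higher by a mean of 0.81, with 9 of 24 members past the threshold adjusted over the list alone and none over all genes (adjusted p = 0.14 with an estimated correlation). Among them Pla2g2a, a secreted phospholipase, was at 3.02, Reg3g, a bactericidal lectin, at 2.50 and Slpi at 0.90. Goblet cell genes were higher by a mean of 0.57, with none of 17 members past either threshold (adjusted p = 0.44 with an estimated correlation). Their largest values were Retnlb at 2.75, Ang4 at 2.08 and Muc2, the main secreted mucin, at 1.02. Retnlb and Ang4 also belong to the antimicrobial list, so these list shifts are not independent. The knockout array numbered 6 had a goblet cell list mean of 8.65, within the wild-type range of 8.63 to 8.89, against 9.65 and 9.73 in the other knockout arrays. Without knockout colon 6 the goblet cell mean was 0.91, and without knockout colon 4 it was 0.37. T and NK cell genes were higher by a mean of 0.39, with 21 of 22 members higher and 2 past the threshold adjusted over the list alone, Cd28 at 0.75 and Ctla4 at 0.73 (adjusted p = 0.14 with an estimated correlation). Neutrophil genes were higher by 0.24 (adjusted p = 0.14 with an estimated correlation), with 2 of 18 members past the threshold adjusted over the list alone, Retnlg at 0.75 and Cd177 at 1.06. STAT3 and acute phase genes were higher by 0.37, and by 0.24 without knockout colon 4 (adjusted p = 0.35 with an estimated correlation), and cytokines and chemokines by 0.19 (adjusted p = 0.11 with an estimated correlation), where Cxcl13, a chemokine that attracts B cells, was at 1.21 and Tnf at 0.48. Genes of mast cells, basophils and eosinophils were higher by 0.30 (adjusted p = 0.46 with an estimated correlation), a call that was also lost without knockout colon 2, where the mean was 0.15, and the wound and stress genes of keratinocytes by 0.26 (adjusted p = 0.90 with an estimated correlation), where Slpi was the 1 member past the threshold adjusted over the list alone. Genes of enteric neurons and glia were lower by a mean of 0.21, with 14 of 18 members lower and Vip at -0.76 the only member past the threshold adjusted over the list alone (adjusted p = 0.26 with an estimated correlation).

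The lists closest to the function of the protease did not shift in colon. Ligands and receptors of the epidermal growth factor receptor family had a mean log2 fold change of 0.08 (camera adjusted p = 0.56), the feedback and target genes of that receptor -0.06 (camera adjusted p = 0.97), the other metalloproteases with their inhibitors -0.02 (camera adjusted p = 0.70) and the other shed substrates -0.02 (camera adjusted p = 0.97). Smooth muscle genes, a measure of how much muscle wall a piece held, had a mean of -0.17 (camera adjusted p = 0.63), and macrophage, monocyte and dendritic cell genes 0.11 (camera adjusted p = 0.56, and 0.044 on the 6 colon arrays alone). The 25 lists that did not shift had means between -0.23 and 0.31. When the 6 colon arrays were fitted alone, with their own and smaller spread, 338 genes passed, 126 higher and 212 lower, and these held all 32, and 16 lists passed by camera. Without 1 array the count ran from 10, for the loss of wild-type colon 3, wild-type colon 5 or knockout colon 4, to 148, for the loss of knockout colon 6, and without both arrays numbered 5 it was 8.

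The second comparison asked which genes differ between knockout and wild-type skin. Skint3, Skint4 and Skint9, members of a family of immunoglobulin-like genes expressed in epidermis and thymus, were near the lower end of the scale in all 3 knockout skin arrays, and Mmp12, the macrophage elastase, was high in all 3. Of 18037 genes, 7 passed the threshold, 3 higher and 4 lower. Mmp12 rose from 3.98 ± 0.67 to 8.18 ± 1.07 (SD, n = 3), an 18.3-fold change (limma adjusted p = 0.0058). Atp6v0d2, a subunit of the vacuolar proton pump found in osteoclasts and macrophages, rose by 2.22 (standard error 0.22), and the peptide hormone gene Pyy by 1.47 (standard error 0.14). Skint9 was at 5.60 ± 1.28 in wild type and 1.07 ± 0.06 in knockout (SD, n = 3), a log2 fold change of -4.52 (standard error 0.45), and Skint3 had a log2 fold change of -4.05 (standard error 0.39) and Skint4 of -2.81 (standard error 0.37). Adam17 was the remaining call. The Skint4 call was lost in 9 of the 12 fits that left out 1 array, which left out a colon array, knockout skin 2, knockout skin 4 or wild-type skin 3, while the calls of Mmp12, Atp6v0d2, Pyy, Skint3 and Skint9 held in all 12. The knockout values of the 3 Skint genes lay between 1.01 and 1.32, and those of the colon arrays, where the genes are not above the floor either, between 0.94 and 1.49. The fold changes of these genes therefore depend on the floor. Of the genes next in p, none passed: Zfp87 at 0.75, Tm4sf19 at 1.21, F7 at 0.80, BC018473 at -2.23 and Adgrg2 at -0.67.

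**Figure D2:**
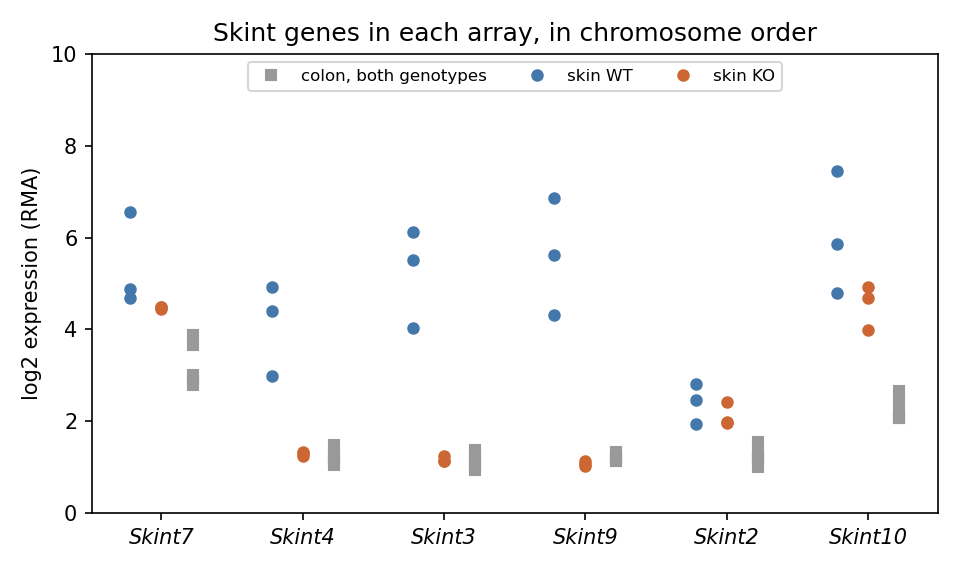
Log2 expression of 6 Skint genes in each array, in their order along the chromosome in the GRCm38.p6 annotation, with the 3 wild-type and 3 knockout skin arrays as circles and the 6 colon arrays as squares. Skint4, Skint3 and Skint9, which are adjacent, lie at 1.32 or below in every knockout skin array, and Skint7 lies between 4.44 and 4.50 there against 4.69 to 6.55 in wild-type skin, and Skint10 between 3.98 and 4.92 against 4.78 to 7.45.

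The skin calls rest on a spread shared with colon that is too small for skin. The median residual SD was 0.156 in colon and 0.256 in skin. Fitted alone, the 6 skin arrays gave 0 genes past the threshold by limma with 237 genes at an unadjusted p under 0.05. Those 237 of 18037 genes are below the share of 0.05 that chance gives. The arrays of the genotypes lay apart in 5.59% of genes in skin and in 27.3% in colon, where chance gives 10%. In colon the array medians lay apart by genotype as well. In data simulated with the spread of skin, 42.0% of the skin calls at a log2 change of 2 were false. Those data held 200 changed genes and noise drawn independently per gene. The share depends on that setting and is not an estimate for the skin calls made here. Without knockout skin 6 the count was 31, and without wild-type skin 5 it was 13.

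Gene lists of skin separated the arrays in a way that did not follow genotype. The list of hair shaft and inner root sheath genes had a mean of 9.25 and 9.06 in knockout skin 2 and 4 and of 8.38 in wild-type skin 5, against 3.99 and 4.12 in wild-type skin 1 and 3 and 4.97 in knockout skin 6. By camera it was the largest of 7 shifts in skin, all upwards, with a mean log2 fold change of 2.26 and 42 of 44 members higher, but none of its members passed over all genes or adjusted over the list alone. Krtap15 was at 4.37, Krt71 at 4.07 and Krtap8-1 at 3.71, and the hair call was lost with an estimated correlation (adjusted p = 0.91). The hair mean was 3.71 without wild-type skin 5 and 3.66 without knockout skin 6. Cell cycle genes followed the same arrays, with a mean of 5.78 to 5.96 in knockout 2, knockout 4 and wild type 5 and of 4.50 to 4.75 in the other 3 skin arrays, and a mean log2 fold change of 0.35 (adjusted p = 0.96 with an estimated correlation). Leaving out any 1 skin array moved the cell cycle mean by more than 1.5 times, between 0.10 and 0.83, and the call was lost without knockout 2, wild type 3 or knockout 4. Melanocyte genes were higher by a mean of 0.85 in all 15 members, with Dct at 1.70 and Slc24a5 at 1.68 (adjusted p = 0.91 with an estimated correlation). The melanocyte mean was 0.45 without wild-type skin 1, where the call was lost, 0.46 without knockout 4, 1.37 without wild type 5 and 1.42 without knockout 6. With the hair list as a covariate the melanocyte mean was -0.025.

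The other 4 shifts in skin were lost with an estimated correlation too. Wound and stress genes of keratinocytes were higher by a mean of 0.91, with 2 of 27 members past the threshold adjusted over the list alone, Sprr2e at 1.42 and Stfa3 at 2.25 (adjusted p = 0.72 with an estimated correlation). Their array means were 5.94 in knockout 2, 5.00 in knockout 4 and 4.04 in knockout 6, the last below the 4.13 and 4.40 of wild type 3 and 5. Without knockout 2 the mean change was 0.43, without knockout 6 it was 1.38, and with the hair list as a covariate it was 0.39. Cytokines and chemokines were higher by a mean of 0.21, with Il1f6 at 1.55 and Ccl22 at 0.76 (adjusted p = 0.073 with an estimated correlation), and neutrophil genes by 0.21, with S100a8 at 1.15 (adjusted p = 0.55 with an estimated correlation). Without wild-type skin 5 both calls were lost, at 0.17 for cytokines and 0.16 for neutrophils, and the neutrophil call was lost without knockout 6 too, at 0.19. Interferon response genes were higher by a mean of 0.34 (adjusted p = 0.96 with an estimated correlation). That value came from knockout skin 6, at 6.29 where the other 5 skin arrays lay between 4.32 and 5.38, and without this array the mean was -0.23. The interferon mean was 0.15 without wild-type skin 1 and 0.25 without wild type 5, where the call was lost, 0.76 without knockout 2 and 0.63 without wild type 3. Basal keratinocyte genes had a mean log2 fold change of -0.16 (camera adjusted p = 0.069) and suprabasal and cornified keratinocyte genes of 0.19 (camera adjusted p = 0.53). The ligands and receptors of the epidermal growth factor receptor family had a mean of 0.04 (camera adjusted p = 0.73), with Btc at -1.13 and Epgn at 0.99. Skeletal muscle genes ran from 7.36 in wild-type skin 5 to 10.7 in wild-type skin 1, both of the same genotype.

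**Figure D3:**
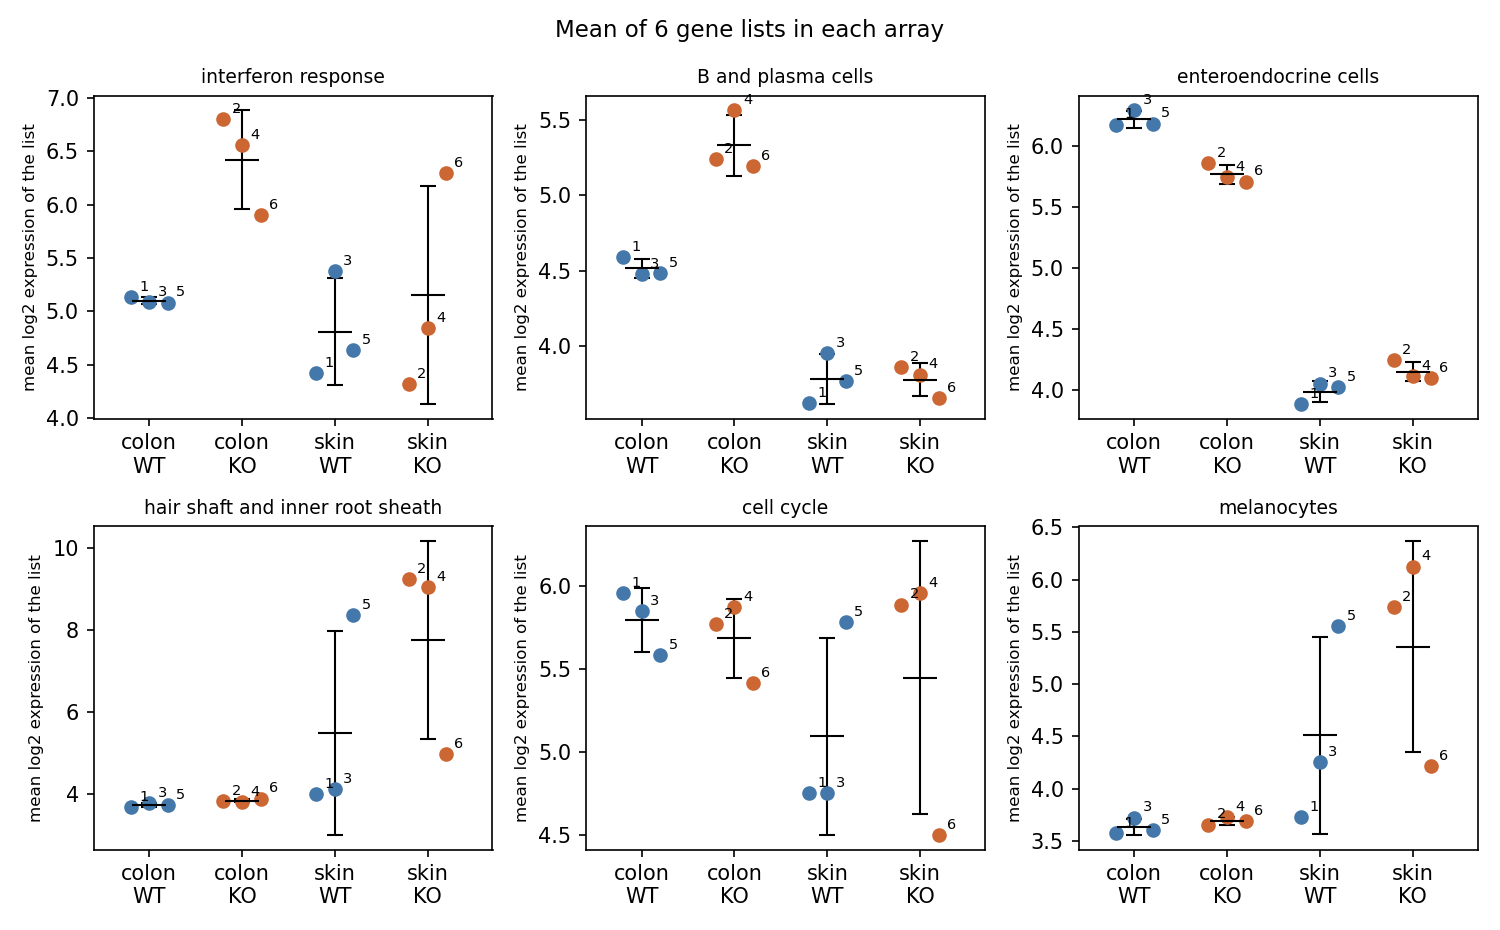
Mean log2 expression of 6 gene lists in each array (points, with the number in the sample title), by tissue and genotype; the horizontal bar is the group mean and the whiskers are 1 SD, and each panel has its own vertical axis. The interferon and B cell lists separate the colon genotypes upwards and the enteroendocrine list downwards, and the hair, cell cycle and melanocyte lists place wild-type skin 5 with knockout skin 2 and 4.

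The third comparison tested whether the knockout effect differed between the tissues. The difference, skin minus colon, passed the threshold for 9 of 18037 genes, 4 positive and 5 negative. Pyy was at 2.26 (standard error 0.20, limma adjusted p = 0.0041), from a change of -0.79 in colon and 1.47 in skin. Kcnf1 at 1.93 and Cyp2c65 at 1.90 were lower in knockout colon, with skin changes of -0.33 and 0.12. Car9, a carbonic anhydrase gene, was at 1.19, from -0.60 in colon and 0.60 in skin, neither of which passed. Skint9 at -4.60 and Skint3 at -4.25 were at the floor in colon, and in skin Cyp2c65 was at 1.44 in wild type and Cd79a at 2.13, both below the 20th percentile of the skin arrays, so these differences restate the change in the other tissue. The Pyy call held in all 12 fits that left out 1 array, and each of the other 8 was lost in 9 to 11 of them. With the number in the titles as a fixed replicate block, 0 genes passed, and Pyy was at a limma adjusted p of 0.20. Cd79a at -2.46, Ido1 at -2.09 and Il17b at -1.26 were higher in knockout colon, with skin changes of -0.30, 0.07 and 0.02. By camera, 13 of 37 lists differed between the tissues, and 2 of these held with an estimated correlation. They were the enteroendocrine list at a mean difference of 0.61 (adjusted p = 0.030 with an estimated correlation) and the list of B and plasma cells at -0.82 (adjusted p = 0.041 with an estimated correlation). The B and plasma cell list lay between 3.62 and 3.95 in every skin array, below the array medians. Its difference therefore largely restates its colon change of 0.81. The enteroendocrine list had a colon change of -0.45, and how far its difference restates that change was not tested. The interferon list differed by -0.98, with a change below that of colon for 27 of 27 genes, and its call was lost (adjusted p = 0.78 with an estimated correlation). It was -0.56 without knockout skin 2 and -1.55 without knockout skin 6. The other 10 calls were lost as well, with adjusted p from 0.51 to 0.97 with an estimated correlation. The number of genes ran from 1 to 38 when 1 array was left out, with 38 for the loss of knockout colon 6.

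Adam17, the targeted gene, was the 1 gene called in both tissues, and no other gene was. Independent lists of these sizes share 0.0049 genes that fall. The overlap is no evidence of a shared effect, since the fall of Adam17 was set by the design. Across all genes, the colon and skin log2 fold changes correlated at a Pearson r of 0.13 and a Spearman rho of 0.15, which describes these arrays, since genes are not independent replicates. Of the 32 colon calls, which include Adam17, 25 had the same sign in skin. This count was not set against the share of all genes, so it does not show shared regulation.

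Genes close to a targeted locus can carry alleles of another strain, so the neighbours of Adam17 were compared with all other genes. Within 20 Mb of Adam17, by the gene order of the GRCm38.p6 annotation, 2 of 150 genes were called in colon against 29 of 17817 elsewhere (two-sided Fisher's exact test, p = 0.027). These were Kcnf1 at -2.26 and the apolipoprotein gene Apob at -1.31. Within 10 Mb the count was 1 of 64 genes (two-sided Fisher's exact test, p = 0.10), and within 40 Mb it was 2 of 200 (p = 0.046 by the same exact test). Fitted on the colon arrays alone, it was 6 of 150 within 20 Mb (two-sided Fisher's exact test, p = 0.064), 5 of 64 within 10 Mb (p = 0.0070 by the same exact test) and 7 of 200 within 40 Mb (p = 0.11 by the same exact test). The genes added within 20 Mb were Mboat2 at 1.55, Rsad2 at 1.43, Pqlc3 at -0.69 and Iah1 at -0.60. Rsad2, counted within 10 Mb too, also belongs to the interferon response list, whose measured genes were all higher in knockout colon. Its call can therefore not be credited to its position. In skin, 0 of 150 genes were called by limma, where 728 of all 18037 genes had an unadjusted p under 0.05. That is below the share of 0.05 that chance gives.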

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

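The tests of the explanations below were chosen after the results were seen, except the counts over other splits of the arrays, which were chosen before.

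The knockout change in skin minus that in colon (log2) passed the threshold for 9 genes and 13 lists. For 4 of these genes the group means of 1 tissue lay below the 20th percentile of its arrays, so the value restates the change in the other tissue: Skint3 and Skint9 lay at 1.38 or below in every colon array, and in skin Cyp2c65 was at 1.44 in wild type and 1.57 in knockout and Cd79a at 2.13 and 1.83. The genes were Pyy (2.26), Kcnf1 (1.93), Cyp2c65 (1.90), Car9 (1.19), Il17b (-1.26), Ido1 (-2.09), Cd79a (-2.46), Skint3 (-4.25) and Skint9 (-4.60). With the number in the titles as a fixed replicate block, 0 genes passed. The lists above 0 were hair shaft and inner root sheath (2.15), melanocytes (0.79), enteroendocrine cells (0.61), cell cycle (0.47), enteric neurons and glia (0.32) and junction and barrier proteins (0.26). Those below 0 were interferon response (-0.98), B and plasma cells (-0.82), goblet cells (-0.69), antimicrobial and host defence proteins (-0.66), MHC class II presentation (-0.57), T and NK cells (-0.32) and mast cells, basophils and eosinophils (-0.24). With an estimated correlation, 2 of the 13 list calls held, those of enteroendocrine cells and of B and plasma cells. Some lists were low in 1 tissue as well. In every skin array the B and plasma cell list lay between 3.62 and 3.95 and the goblet cell list between 3.77 and 4.18. The hair list lay between 3.68 and 3.89 in every colon array. The differences of these lists therefore mostly restate the change in the other tissue. The junction and barrier and mast cell calls were also lost with quantile normalization within each tissue and without both arrays numbered 5. Leaving out 1 array ended the call in 6 fits for melanocytes (0.40 to 1.36), in 5 for cell cycle (0.21 to 0.94), in 5 for junction and barrier proteins (0.11 to 0.42) and in 1 for enteric neurons and glia (0.25 without wild-type skin 1). It ended the MHC class II call without knockout skin 2 (-0.056) and wild-type skin 3 (-0.22), where it was -0.92 without knockout skin 6 and -0.86 without wild-type skin 1, and the antimicrobial call without wild-type skin 3 (-0.50) and knockout skin 6 (-0.65), where it was -0.43 without knockout colon 4. The mast cell call ended without knockout colon 2 (-0.092), wild-type colon 5 (-0.20), knockout skin 2 (-0.11) and wild-type skin 3 (-0.030), and the value was -0.39 without wild-type skin 1. The hair list ran from 1.40 without wild-type skin 1 to 3.59 without wild-type skin 5, goblet cells reached -1.03 without knockout colon 6, and T and NK cells were at -0.18 without wild-type skin 3 and -0.20 without knockout skin 2, with these 3 calls held. Among 10161 clusters with several gene symbols or none, which enter no comparison of the report, 6 passed the threshold in colon, 3 higher and 3 lower.

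For colon, 1 of the 10 splits of the 6 arrays gave as many as 32 genes, the real one, and the highest of the others gave 0. Fitted on the colon arrays alone, 1 of the 10 splits gave as many as 338, the real one, and the highest of the others gave 0. For skin, 3 of the 10 splits gave 7 genes or more, and the highest of the others gave 2173. With 10 splits no share under 0.05 can be reached. The skin split with 2173 genes set the numbers 1, 3 and 6 against 2, 4 and 5, many times the real count, which points to a structure of the skin arrays that is not genotype. For the difference between tissues, 12 of 100 splits gave 9 genes or more, and the highest of the others gave 750, so chance is not excluded for that count.

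In skin, the hair list was high in knockout 2, knockout 4 and wild type 5. Genotype alone is argued against, since wild type 5 lay above knockout 6 by 3.40 on the log2 scale. Exchanged labels of skin 5 and 6 are argued against as well, since Adam17 was higher in the array labelled wild type 5 than in that labelled knockout 6 by 1.01. A candidate explanation is that the follicles of the pieces differed in growth phase or number apart from genotype. With the hair list as a covariate, the mean change of the cell cycle list went from 0.35 to -0.29. Both lists were high in the same arrays, so this fit could hardly give another result and does not tell the explanations apart. Wild type 5 was the only skin array with the male pattern (Xist 2.86, against 7.97 to 9.17 in the others). Knockout 2 and 4, without that pattern, had a high hair list too, and an effect of sex was not tested. An effect of the knockout on the hair cycle, with knockout 6 and wild type 5 at other phases, stays open and was not tested.

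In colon, the interferon, B cell and other immune lists were higher in knockout, and of these the call of B and plasma cells held with an estimated correlation (adjusted p = 0.021) and those of interferon (0.25), T and NK cells (0.14) and neutrophils (0.14) did not. For the interferon list, the wild-type sample with a male pattern is argued against as the cause, since its mean change was 1.31 without the arrays numbered 5. The B and plasma cell mean ran from 0.70 to 0.88 over the alternatives, which include that fit. After normalization the colon array medians lay between 4.15 and 4.19 in wild type and between 4.25 and 4.28 in knockout. The 20th percentiles lay between 2.07 and 2.11 in wild type and between 2.20 and 2.23 in knockout. This shift followed genotype, and small rises of genes near the floor cannot be told apart from it. It is small beside the interferon change, so centring each array could move the interferon mean little, and it gave 1.36. Centring does not test other effects of the normalization. More lymphoid tissue in the knockout pieces, as a biological or a sampling difference, cannot be told apart from a response of the cells already there, because whole tissue was measured: the T and NK cell list was higher too, by 0.39. An effect of the knockout itself stays among the open explanations.

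In skin, Skint3, Skint4 and Skint9 were near the floor in all 3 knockout arrays. The state of the follicles is argued against as the whole cause, since the mean change of the 3 genes went from -3.79 to -3.29 with the hair list as a covariate (standard error 0.61), although no gene passed on the skin arrays alone with or without it. Fewer keratinocytes in the knockout pieces are argued against, since the basal keratinocyte list had a mean log2 fold change of -0.16. A candidate explanation is another allele at these 3 genes, which are adjacent in the GRCm38.p6 annotation, in the knockout animals. Within 40 Mb of Adam17, 0 of 200 genes were called in skin. Such an allele would therefore be a strain difference away from the targeted locus. The highest knockout skin array minus the highest colon array was -0.13 at most among the 3 genes, so no signal above that of colon was left. Skint7 was also lower in every knockout skin array (4.44 to 4.50) than in every wild-type one (4.69 to 6.55), short of the threshold. Skint2 (1.96 to 2.42 against 1.94 to 2.81) and Skint10 (3.98 to 4.92 against 4.78 to 7.45) overlapped between the genotypes. Skint genes may share probes, so Skint7 does not decide whether the lower values were confined to the 3 genes. An allele that the probes miss, a deletion and silencing of the genes by the knockout cannot be told apart with these arrays, since each would leave the values at the floor.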

How the results depend on the processing

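Fits without the arrays numbered 5, with the hair list as a covariate and without colon array 6 were chosen after seeing the data, as were the fits of the Adam17 neighbours on colon arrays alone. So were, for the gene lists only, centring on the median and the number as a fixed block. The 32 colon genes became 1335 with array weights, 338 on the 6 colon arrays alone, 1654 on those less the array numbered 6, and 8 without the arrays numbered 5; leaving out 1 array gave 10 to 148. The 7 skin genes became 1164 with array weights and 2 with the stricter filter. On the 6 skin arrays alone they became 0, with or without the hair list as a covariate. Without that covariate, 237 genes had an unadjusted p under 0.05 in limma, fewer than chance gives. For skin, leaving out 1 array gave 5 to 31. The 9 genes of the difference became 1048 with array weights, 1 with the stricter filter and 5 without the arrays numbered 5; leaving out 1 array gave 1 to 38. The array weights ran from 0.25 to 4.98, and knockout skin 4 took the highest. The overlap of 1 gene became 64 with array weights, 2 with every cluster kept, and 0 with the stricter filter, on the tissues alone and without the arrays numbered 5; leaving out 1 array gave 0 to 1. The 2 neighbours of Adam17 became 1 at 10 Mb, and on the colon arrays alone 6, 5 at 10 Mb and 7 at 40 Mb. Apart from the replicate block, the settings not named here kept these counts within 1.5 times. With the stricter filter, Skint3, Skint4, Skint9 and Atp6v0d2 were no longer tested, and Adam17 in skin missed the threshold (limma adjusted p = 0.078). For the difference, Skint3, Skint9 and Cyp2c65 were no longer tested there. Apart from these losses and the settings that test fewer arrays, the cause was not tested.

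The log2 fold change of Adam17 in colon was -2.24 without the arrays numbered 5, short of the threshold, and -2.34 to -2.04 with 1 array left out. In skin it missed the threshold at -2.01 with the stricter filter and on the skin arrays alone, at -2.20 without the arrays numbered 5 and at -1.61 with the hair covariate, and ran from -2.33 to -1.79 with 1 array left out. Its direction held in every setting.

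Lists past the threshold fell from 12 to 2 in colon, from 7 to 0 in skin and from 13 to 2 for the difference, both with an estimated correlation and with fry. They rose to 19 on the colon arrays less number 6 and to 12 in skin with the hair covariate; with 1 array left out they ran from 12 to 14 in colon, 6 to 14 in skin and 10 to 15 for the difference. Reversed list means arose in skin, mostly where a list missed the threshold at first. Without wild-type skin 1 collagens and extracellular matrix were at -0.70 (1 array left out: -0.70 to 0.51), skeletal muscle at 0.67 (-0.99 to 0.67) and endothelium at -0.31 (-0.31 to 0.42), and for the difference collagens were at -0.57 (-0.57 to 0.64) and skeletal muscle at 0.65 (-1.01 to 0.65). Without knockout skin 2 suprabasal keratinocytes were at -0.14 (-0.14 to 0.50) and macrophages, monocytes and dendritic cells at 0.48 (-0.57 to 0.49, the last without wild-type skin 3). Without knockout skin 6 the interferon list was at -0.23 (-0.23 to 0.76). With the hair covariate they were -0.29 for cell cycle, 1.01 for skeletal muscle, -0.025 for melanocytes and 0.35 for macrophages, monocytes and dendritic cells. The cause was not tested. No named gene reversed; of its settings, 267 lost and 133 gained a call, and 2056 changed none.

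The labels do not say that a number marks a mouse. Deviations of the same number in both tissues correlated between -0.06 and 0.10 across genes, and 2 of 6 numbers correlated best with their own. The arrays numbered 5 had the male pattern in both tissues, so these correlations do not exclude a shared mouse. As a fixed replicate block the number left 0 genes for the difference, and as a random block (correlation 0.072) 33, 7 and 11 genes for colon, skin and the difference.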

Other observations

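Families of genes that share a symbol stem were compared in a search chosen after the data were seen, over 573 families of 5 or more genes in each tissue. By camera 21 families passed in colon and 6 in skin, and 0 passed with an estimated correlation (adjusted p = 0.78 or more in colon and 0.99 in skin). In knockout colon the lowest p was that of the Gimap family, GTPases of lymphocytes, with all 7 members higher and a mean log2 fold change of 0.61 (camera adjusted p = 8.4e-05, adjusted p = 0.78 with an estimated correlation). The Slfn family had a mean of 0.60 with 8 of 9 members higher, the Ces family of carboxylesterases -0.55 over 16 members, of which 2 fell, and the Fmo family of flavin monooxygenases -0.77 with all 5 members lower (adjusted p = 0.78 for each with an estimated correlation). The others with higher means were Cd, Oas, Ifit, Gbp, Apol, Cxcl, Muc, Lhx, Tas, Wnt, Col and Prss, from 0.11 for Prss to 1.11 for Ifit, and those with lower means were Abcg at -0.50, Mettl at -0.22, Nup at -0.21, Ift at -0.20 and Vps at -0.16. In skin the lowest p was that of the Krtap family of hair keratin-associated proteins, with 43 of 44 members higher and a mean of 2.59 (camera adjusted p = 2.0e-16, adjusted p = 0.99 with an estimated correlation). The Skint family was next, with 6 of 6 members lower and a mean of -2.35 (camera adjusted p = 2.0e-13, adjusted p = 0.99 with an estimated correlation), and the others were Krt at 1.06, Sprr at 0.82, Lce at 0.45 and Rpl at 0.11. No family turned its direction with arrays centred on the median or with quantile normalization within each tissue.

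The gene BC018473 was low in all 6 knockout arrays of both tissues. In colon it lay between 2.62 and 2.84 in knockout and between 4.13 and 4.89 in wild type, and in skin between 2.61 and 2.71 in knockout and between 4.18 and 5.98 in wild type. Its change passed the threshold in neither tissue over all 12 arrays (limma adjusted p = 0.10 in colon and 0.18 in skin), and it passed in colon when the 6 colon arrays were fitted alone (log2 fold change -1.91, limma adjusted p = 0.0030) and in both tissues with array weights. Over the alternatives, its limma adjusted p ran from 9.2e-04 to 0.47 in colon and from 0.0039 to 1.00 in skin.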
